A study of Mus musculus with 6 samples.

How the data were processed

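RNA was taken from tibialis anterior muscle of 3 wild-type (WT) mice and 3 mice with a deletion of Dmd exon 51 (dEx51), and stranded mRNA libraries were made, per the labels. The labels call the libraries of each genotype biological replicates. Whether samples came from separate litters or days is not given in the sources used here. The submitters' processing notes name FastQC 0.11.4, featureCounts 1.6.0, edgeR 3.30.1 and the genome build GRCm38 (mm10). The aligner, the strand setting of the counting and the annotation release are not given in the sources used here, so overlapping genes on opposite strands are treated as uncertain.

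The authors deposited raw read counts per gene for 54232 genes, whole numbers that were not normalized, with the exon length of each gene. The deposited RPKM values, scaled to gene length and library total, cover a subset of genes chosen by a filter not given in the sources used here. They lie above 0 where the count is 0, so they were adjusted by a step that is likewise not given. The authors' deposited table of the comparison holds log2 fold changes and average log2 CPM, the likelihood-ratio statistic (a score), a p-value and adjusted p-value, and the −log10 of the p-value, per the file headers. Column sums of the deposited counts were 20136164, 21020353 and 15681945 in WT 1 to 3 and 20105817, 19262344 and 18571038 in dEx51 4 to 6. Of the gene IDs, 54165 were found in GENCODE release M21 on GRCm38, 52697 of them with the same exon length, and coordinates were taken from that release. A total of 98 symbols stand for more than 1 gene ID. The count floor covers counting error only, and intervals of list values are over genes. The SE of a log2 fold change was back-calculated as its absolute value divided by the square root of the F statistic of the main test. The interval of Dmd comes from this SE.

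The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the default expression filter by group and Benjamini-Hochberg adjustment over the 14335 genes left. Tests were two-sided, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.155. Gene lists were compared with other genes by camera with a preset correlation of 0.01, adjusted over 30 lists with at least 3 tested members out of 32 lists. The 32 lists hold 469 genes, and 423 were tested. The design, the lists and the alternatives were fixed before the data were examined, apart from those said to be chosen later. Named genes are Dmd, the 10 largest rises and 10 largest falls among called genes of at least 5 CPM with no overlap between groups, leaving out predicted genes and pseudogenes, and up to 4 members of each list with the smallest adjusted p, 3 in the direction of the list median and 1 in the other. Where no member passed, up to 2 members could be named with values only. The rule gave 105 genes, of which some are not reported here, and any other named gene is said to be chosen after its values were seen.

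Alternatives were DESeq2 size factors, library size alone, TMM without the 20 most abundant genes, no filter and a stricter filter, DESeq2 1.42.0, the edgeR exact test, limma-voom (limma 3.58.1) with and without quality weights, a robust fit, a replicate block, each library left out in turn, limma-trend on log2 of the deposited RPKM with a pseudocount of 0.1 or 1, stricter thresholds, camera with an estimated correlation, and fry. The likelihood-ratio test and the removal of WT 1 with dEx51 4 were added after seeing the data. A chi-square comparison of counts within each group gave 8.08 to 42.9 per degree of freedom, so no library repeats another.

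The test was tried on simulated counts for the dEx51 against WT comparison, with 200 changed genes in each of 3 runs. With gene-wise dispersions (14051 genes) it recovered 19.5% of 1.5-fold, 65.4% of 2-fold and 94.7% of 4-fold changes, and 10.4% of its calls were false (40 of 384), above the nominal 5%. With trended dispersions (14080 genes) it recovered 33.8%, 79.1% and 97.4%, and 3.48% of calls were false (15 of 431). The simulated rises and falls were drawn with equal odds and were far fewer than the 2309 higher and 1701 lower genes called in the data. The p-value needed for a call depends on that number, so these rates hold for the simulated setting and not for the real comparison.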

Results

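Poly(A)-selected, strand-marked RNA sequencing libraries were made from the tibialis anterior, a fast-twitch muscle of the lower hind leg, of C57BL6 mice aged 1 month. There were 3 wild-type libraries (WT 1, WT 2 and WT 3) and 3 libraries from mice that lack exon 51 of Dmd (dEx51 4, dEx51 5 and dEx51 6), and the labels call them biological replicates. The comparison asks how loss of this exon changes gene expression in the muscle. Totals of reads assigned to genes were 20136164, 21020353 and 15681945 in WT 1 to 3 and 20105817, 19262344 and 18571038 in dEx51 4 to 6. Values below are library-scaled counts (CPM, the usual per-library rate of counts) scaled by the trimmed mean of M values (TMM), as mean ± SD over the 3 libraries of a group. Log2 fold changes are dEx51 over WT with a standard error (SE) back-calculated from the F statistic of the test. The first principal component held 72.2% of the variance and separated the genotypes, with dEx51 6 (30.6) nearer to WT (-58.1 to -38.1) than dEx51 4 (51.6) and dEx51 5 (55.1). All 6 libraries held 0 to 3 Xist counts and 1827 to 2989 counts of the Y-linked gene Ddx3y.

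Dmd encodes dystrophin, which links the actin cytoskeleton of the muscle fibre to the extracellular matrix. Its transcript was lower in every dEx51 library, at 47.7, 46.4 and 51.1 CPM against 235, 249 and 266 CPM in WT. The group means were 48.4 ± 2.46 and 250 ± 15.3 CPM (n = 3 each), so dEx51 held 19.3% of the WT level. The log2 fold change was -2.37 (SE 0.0944, 95% interval -2.59 to -2.15, edgeR adjusted p = 2.77e-05). The gene (ENSMUSG00000045103) lies on the forward strand of chromosome X at 82948870 to 85206141 in GRCm38. Exon 51 of its 79-exon transcript model Dmd-203 spans 84474134 to 84474366, is coding over its whole length and has 233 bases, which leaves a remainder of 2 when divided by 3. Counts summed over the whole gene cannot show reads of that exon on their own, so the lower level checks the genotype labels only through the transcript as a whole.

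Of 14335 genes tested, 2309 were higher and 1701 lower in dEx51 muscle (edgeR quasi-likelihood test, adjusted p under 0.05), and 10325 were not called. Rises reached further than falls: 1346 genes rose by at least 1 log2 unit and 195 fell by as much. In 45.5% of genes tested no dEx51 library overlapped any WT library, where chance gives 10% for a single gene with 3 against 3. Genes vary together, so the gap between these shares is not a test against chance. The smallest exact permutation p for 3 against 3 libraries is 0.1. The split between higher and lower genes rests on the scaling. TMM factors were 0.869 to 0.898 in WT and 1.04 to 1.19 in dEx51, and scaling to library size alone moved the median log2 fold change of all genes by 0.35 and gave 5394 higher and 334 lower genes. Fold changes below are therefore relative to the bulk of the genes tested. Leaving out WT 2 gave 1346 higher and 663 lower genes, and leaving out dEx51 4 or dEx51 5 gave 986 or 759 lower genes. The authors' deposited table, which has a likelihood-ratio column, calls 2666 genes higher and 2629 lower among 13958 genes. A likelihood-ratio test run here, added after seeing the data, gave 2509 higher and 1860 lower. The cause of the remaining gap was not tested. By the authors' deposited table, 2223 of the genes higher here and 1661 of those lower here were called in the same direction, 0 genes were called in opposite directions, and the log2 fold change of Dmd is -2.40.

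**Figure D1:**
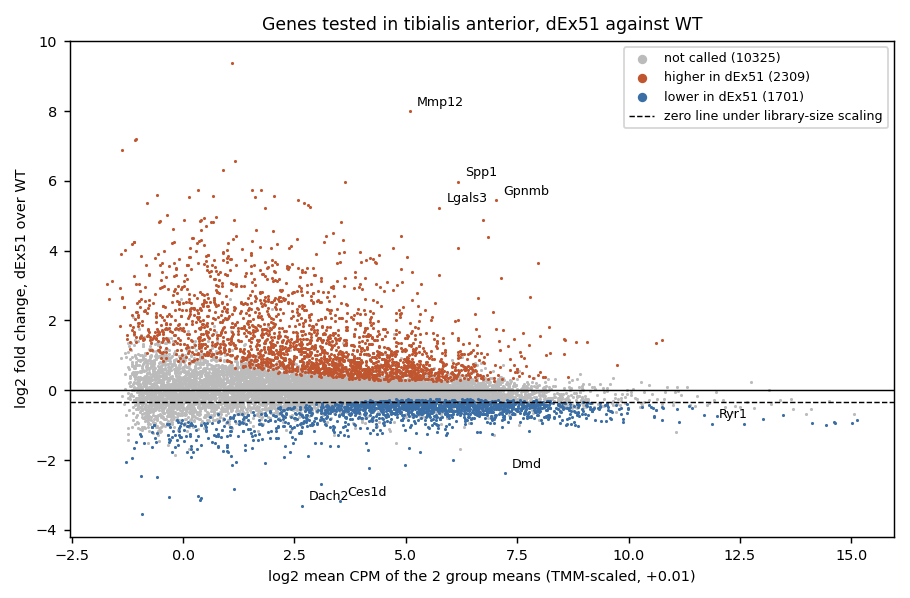
Each point is a gene tested, with the log2 of the mean CPM of both groups on the x axis and the log2 fold change of dEx51 over WT on the y axis. Orange points are the 2309 higher genes, blue points the 1701 lower genes, and the dashed line shows where a fold change of 0 would lie if libraries were scaled to their totals alone.

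The 10 largest rises by the naming rule included Mmp12, Spp1, Gpnmb, Lgals3 and Mymk. Among genes of at least 5 CPM with no overlap between libraries, Mmp12, the macrophage metalloelastase gene (chromosome 9, 7344381 to 7369499), rose most, from 0.250 ± 0.215 to 68.0 ± 53.7 CPM (log2 fold change 8.003, SE 0.909, edgeR adjusted p = 0.00121). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), rose from 2.33 ± 1.35 to 142 ± 42.6 CPM (5.97, SE 0.395). The membrane glycoprotein gene Gpnmb rose from 5.79 ± 1.03 to 253 ± 112 CPM (5.44, SE 0.369), and Lgals3, which encodes galectin-3, rose from 2.83 ± 0.695 to 105 ± 16.6 CPM (5.23, SE 0.20). Atp6v0d2, Il7r, Trem2, Ctss and Itgax rose by 4.82 to 5.98 log2 units. Mymk encodes myomaker, a membrane protein needed for fusion of myoblasts, and rose from 0.385 ± 0.292 to 14.0 ± 2.01 CPM (5.25, SE 0.342).

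The largest falls, apart from Dmd, were in Dach2, a transcriptional cofactor gene on chromosome X (113297510 to 113836386), from 11.5 ± 2.01 to 1.15 ± 0.170 CPM (log2 fold change -3.31, SE 0.204, edgeR adjusted p = 2.55e-04). The carboxylesterase gene Ces1d (chromosome 8, 93166068 to 93197838) went from 20.7 ± 3.46 to 2.31 ± 0.846 CPM (-3.18, SE 0.262). Ppp1r1a, which encodes a protein phosphatase inhibitor, had a log2 fold change of -2.68 (SE 0.194), and the phosphatase gene Dusp26 of -2.15 (SE 0.129). Efcab6, Ccdc85c and Cdh23 had log2 fold changes of -1.87, -1.78 and -1.60. Cyp26b1, a retinoic acid hydroxylase gene, was at 29.6 ± 26.1 and 6.34 ± 2.49 CPM (-2.23, SE 0.634), and Dgat2, which acts in triglyceride synthesis, at 51.3 ± 25.2 and 16.3 ± 8.94 CPM (-1.65, SE 0.458). WT 2 held the highest value of both genes, 58.9 and 76.6 CPM. Scaled to library size alone the call of Dgat2 ended (-1.26). The call of Cyp26b1 ended without WT 2 (-1.23), WT 3 (-2.43), dEx51 4 (-2.50), dEx51 5 (-1.93) or dEx51 6 (-2.30), and that of Dgat2 without WT 2 (-1.24), WT 3 (-1.66), dEx51 4 (-1.55) or dEx51 6 (-1.35). Over all 21 alternatives run for each gene, including other methods and scalings, Cyp26b1 lost its call in 10 and Dgat2 in 7.

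Genes of muscle formation rose together. Of 14 embryonic and neonatal muscle genes tested, 11 rose and 0 fell (median log2 fold change 2.07, camera adjusted p = 4.41e-23, adjusted p = 0.129 with an estimated correlation), and adjusted over the list alone 11 rose and 1 fell. Chrna1, the alpha subunit of the acetylcholine receptor, rose from 14.5 ± 0.676 to 71.8 ± 1.81 CPM (2.31, SE 0.0847). The embryonic and cardiac troponin gene Tnnt2 rose from 2.90 ± 1.06 to 36.7 ± 5.54 CPM (3.68, SE 0.233), and Ankrd1, a stretch-responsive gene, from 9.81 ± 2.00 to 97.6 ± 12.4 CPM (3.31, SE 0.165). Myh3, the embryonic myosin heavy chain, was chosen after its values were seen and rose from 8.14 ± 1.46 to 136 ± 53.4 CPM (4.07), while the neonatal Myh8, likewise chosen, was at 977 ± 25.5 and 744 ± 142 CPM and was not called (-0.39). Of 13 satellite cell and myogenic genes tested, 7 rose and 0 fell, or 9 and 0 adjusted over the list alone (median 0.96, camera adjusted p = 5.19e-07, adjusted p = 0.129 with an estimated correlation). Myog, the transcription factor of terminal differentiation, rose from 2.60 ± 0.834 to 35.8 ± 14.8 CPM (3.75, SE 0.349). Mymx, the partner of Mymk, was at 0.0423 ± 0.0375 CPM (2 counts in all) in WT and 2.47 ± 0.570 CPM in dEx51. Pax7, the satellite cell transcription factor, was at 4.19 ± 0.744 and 6.02 ± 0.628 CPM and was not called (0.53). Pax7 was chosen after its values were seen.

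Macrophage genes rose in nearly every case. Of 18 macrophage and monocyte genes, 17 rose and 0 fell, both over all genes and adjusted over the list alone (median log2 fold change 3.66, camera adjusted p = 9.19e-34, adjusted p = 0.129 with an estimated correlation). They include Lgals3 and Spp1, given above, and the receptor gene Trem2, which rose from 0.346 ± 0.157 to 13.6 ± 3.51 CPM (5.30, SE 0.335). The member that was not called was the scavenger receptor gene Cd163 (0.11), named after its values were seen. Of 14 complement genes, 11 rose and 0 fell, the same counts as adjusted over the list alone (median 1.38, camera adjusted p = 1.03e-08, adjusted p = 0.129 with an estimated correlation), among them the receptor genes C3ar1 (3.88, SE 0.268) and C5ar1 (2.43, SE 0.259) and C1qc (2.21, SE 0.291). Of 7 chemokine and cytokine genes tested from 19 listed, 6 rose and 0 fell, also adjusted over the list alone (median 2.43, camera adjusted p = 5.16e-05, adjusted p = 0.212 with an estimated correlation). Ccl6 rose from 6.89 ± 3.87 to 36.4 ± 12.5 CPM (2.43, SE 0.401). Il1rn, the interleukin 1 receptor antagonist gene, had 0 counts in WT and 284 in dEx51, at least 71.5-fold higher against a floor of 3 counts over the WT group, and the list median with this bound was again 2.43. Antigen presentation genes had 8 of 13 higher and 0 lower, or 11 and 0 adjusted over the list alone (median 1.51, camera adjusted p = 4.76e-04, adjusted p = 0.438 with an estimated correlation), with Ciita, the regulator of class II genes, at 1.76 (SE 0.353). Lymphocyte and granulocyte lists had 2 tested members each out of 15, too few for a set test. Cd4 (2.29, SE 0.389) and Csf3r (4.06, SE 0.623) rose. Cd3e was called (1.57, SE 0.441) and lost its call without WT 1 (1.23), WT 2 (1.45), dEx51 4 (1.62), dEx51 5 (1.71) or dEx51 6 (1.37). These 3 genes rose from 0.356 or less to between 0.977 and 4.73 CPM. In dEx51 6 the 17 macrophage genes reached a median of 54.9% of the rise seen in the other dEx51 libraries, with single genes from 25.5% to 192%. Lgals3 was lowest in dEx51 6, at 85.4 CPM against 115 and 113 CPM in dEx51 4 and 5. Gpnmb was highest there, at 369 CPM against 144 and 245 CPM, as was Mmp12, which is outside the list, at 127 CPM against 55.3 and 21.7 CPM.

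Cell cycle genes rose with a wide spread within the dEx51 group. Of 20 tested, 18 rose and 0 fell, or 19 and 0 adjusted over the list alone (median log2 fold change 2.92, camera adjusted p = 1.68e-08, adjusted p = 0.376 with an estimated correlation). Top2a, which encodes a DNA topoisomerase, stood at 1.16 ± 0.341 CPM in WT and at 29.0, 33.9 and 5.30 CPM in dEx51 4, 5 and 6 (4.31, SE 0.708). The proliferation marker Mki67 stood at 2.53 ± 1.05 CPM in WT and at 42.7, 50.8 and 9.55 CPM in the same libraries (3.79, SE 0.636). Rrm2, a ribonucleotide reductase gene, rose from 2.33 ± 0.841 to 17.7 ± 9.06 CPM (2.96, SE 0.424).

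Matrix genes rose as a group, while the main fibrillar collagen I genes were not called. Of 26 extracellular matrix genes, 17 rose and 0 fell, or 19 and 0 adjusted over the list alone (median log2 fold change 1.22, camera adjusted p = 7.21e-12, adjusted p = 0.273 with an estimated correlation). Bgn, the proteoglycan biglycan, rose from 95.2 ± 9.17 to 299.6 ± 40.3 CPM (1.65, SE 0.129), Col14a1 from 21.4 ± 4.11 to 66.5 ± 6.38 CPM (1.64, SE 0.149) and Fn1, which encodes fibronectin, from 133 ± 32.7 to 387 ± 18.2 CPM (1.54, SE 0.179). Col1a1 (0.24, 1142 ± 423 and 1351 ± 146 CPM) and Col1a2 (0.16) were not called, whereas Col3a1 was at 927 ± 292 and 2496 ± 234 CPM (1.43), 3 genes chosen after their values were seen. Of 10 markers of fibro-adipogenic progenitors, the resident mesenchymal cells of muscle, 4 rose and 0 fell, or 5 and 1 adjusted over the list alone (median 0.40, camera adjusted p = 0.00513, adjusted p = 0.376 with an estimated correlation). They were led by Mfap5 (1.39, SE 0.130), Dpt (1.07, SE 0.102) and Pdgfra (0.82, SE 0.118). Of 16 TGF-beta pathway genes, 7 rose and 0 fell, also adjusted over the list alone (median 0.32, camera adjusted p = 0.00134, adjusted p = 0.129 with an estimated correlation). Ltbp2 rose from 0.536 ± 0.405 to 6.61 ± 0.731 CPM (3.69, SE 0.381) and Tgfb1 by 1.58 (SE 0.204).

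Markers of vessels and of myelinating Schwann cells fell. Of 15 endothelial genes, 0 rose and 10 fell, or 0 and 11 adjusted over the list alone (median log2 fold change -0.53, camera adjusted p = 5.16e-05, adjusted p = 0.212 with an estimated correlation). Tek and Tie1, receptor tyrosine kinases of endothelium, had log2 fold changes of -0.53 (SE 0.0918) and -0.59 (SE 0.109), and Robo4 of -0.69 (SE 0.132). Of 10 pericyte and smooth muscle genes, 0 rose and 5 fell, also adjusted over the list alone (median -0.44, camera adjusted p = 0.00577, adjusted p = 0.273 with an estimated correlation). Myh11, the smooth muscle myosin, was at 107 ± 5.94 CPM in WT and 54.6 ± 7.21 CPM in dEx51 (-0.97, SE 0.113), and Rgs5 at 884 ± 66.8 and 549 ± 58.5 CPM (-0.69, SE 0.120). Of 9 Schwann cell genes, 0 rose and 6 fell, also adjusted over the list alone (median -0.91, camera adjusted p = 1.77e-04, adjusted p = 0.129 with an estimated correlation). Prx, which encodes periaxin, went from 9.26 ± 0.950 to 4.52 ± 0.0414 CPM (-1.04, SE 0.136). Of 5 erythroid genes, 0 rose and 3 fell, or 0 and 5 adjusted over the list alone (median -0.86, camera adjusted p = 0.0119, adjusted p = 0.425 with an estimated correlation), and the list lost its call without dEx51 6 (median -0.69). Adipocyte genes (0 of 10 called, 0 adjusted over the list alone) and tendon genes (1 of 8 called, Thbs4 at 1.07, also adjusted over the list alone) did not pass the set test (medians -0.19 and -0.37, camera adjusted p = 0.504 and 0.915). The adipocyte median was 0.14 without dEx51 4, -0.52 without dEx51 5, -0.10 without WT 3, -0.05 without dEx51 6 and 0.17 under library-size scaling. The tendon median was -0.23, -0.66 and -0.13 without WT 1, WT 2 and WT 3. Scaled to library size alone, the medians of the endothelial, pericyte, Schwann cell and erythroid lists were -0.17, -0.10, -0.57 and -0.50. In these lists 1, 2, 4 and 0 members were called lower and 0, 1, 1 and 0 called higher. The calls of Tek, Tie1 and Robo4 ended (-0.17, -0.23 and -0.33). These 4 lists again passed the set test as lower than other genes. A shift shared by most genes largely cancels in that comparison, so the pass does not test the scaling.

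Transcripts of mitochondrial energy metabolism fell. Of 22 nuclear genes of oxidative phosphorylation, 0 rose and 18 fell, or 0 and 22 adjusted over the list alone (median log2 fold change -0.44, camera adjusted p = 5.00e-08, adjusted p = 0.273 with an estimated correlation). Cox6a2, a muscle subunit of cytochrome oxidase, went from 340 ± 66.1 to 187 ± 4.68 CPM (-0.86, SE 0.146), and Uqcrc1 from 696 ± 27.3 to 465 ± 28.9 CPM (-0.58, SE 0.0989). Of 18 fatty acid oxidation genes, 0 rose and 13 fell, or 0 and 15 adjusted over the list alone (median -0.53, camera adjusted p = 9.25e-07, adjusted p = 0.376 with an estimated correlation). Acadm, the medium-chain acyl-CoA dehydrogenase, went from 361 ± 21.7 to 221 ± 17.8 CPM (-0.71, SE 0.101), and Etfdh from 194 ± 17.6 to 125 ± 8.71 CPM (-0.64, SE 0.103). Of 14 genes of glycogen use and glycolysis, 0 rose and 3 fell, also adjusted over the list alone (median -0.28, camera adjusted p = 0.00972, adjusted p = 0.529 with an estimated correlation), with Hk2, a hexokinase gene, at -0.67 (SE 0.130). The glycolysis list lost its call without dEx51 5 (median -0.17). The share of all counts from the mitochondrial genome was 20.3 ± 0.816% in WT and 14.0 ± 0.720% in dEx51, with no overlap between the groups. Scaled to library size alone, the medians of the oxidative phosphorylation and fatty acid lists were -0.08 and -0.17, with 1 member of each called lower, and the glycolysis median turned to 0.06. These 3 lists again passed the set test as lower than other genes, a comparison in which a shift shared by most genes largely cancels. The pass therefore does not test the scaling. The calls of Uqcrc1, Etfdh and Hk2 ended under that scaling (-0.23, -0.28 and -0.32).

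Among contractile genes the slow isoforms moved apart. Of 12 slow fibre genes, 5 rose and 2 fell, or 6 and 3 adjusted over the list alone, and the list did not pass the set test (median log2 fold change 0.24, camera adjusted p = 0.0766). It passed without WT 2 (0.31) or dEx51 5 (0.21), and without dEx51 6 the median was 0.48 with no call. Tnni1, Tnnt1 and Atp2a2, which encode slow troponins and the slow calcium pump and are also expressed in developing muscle, rose by 3.74 (SE 0.359), 1.95 (SE 0.265) and 1.08 (SE 0.116), whereas the myosin gene Myh7b fell (-1.23, SE 0.184). The slow myosin Myh7, chosen after its values were seen, also fell (-2.08), from 5.73 ± 3.51 to 1.36 ± 0.173 CPM. Of 13 fast fibre genes, 0 rose and 1, Mylk2, fell (-0.59, SE 0.173), with 0 called adjusted over the list alone and no call of the list (median -0.28, camera adjusted p = 0.0678). Without dEx51 6 the fast fibre list passed the set test (median -0.42), and Mylk2 lost its call without WT 1 (-0.64), WT 2 (-0.50), WT 3 (-0.66), dEx51 4 (-0.50) or dEx51 5 (-0.49). The fast troponin gene Tnnc2 had 28 counts in WT and 54 in dEx51, and 592 of its 800 exon bases lie opposite exons of Ube2c, so its level is uncertain (named after its values were seen). Of 14 excitation-contraction coupling genes, 1 rose and 4 fell, also adjusted over the list alone, with no call of the list (median -0.31, mean 0.00, camera adjusted p = 0.166). Without dEx51 6 the list passed (median -0.44). Under library-size scaling the fast fibre and coupling medians turned to 0.06 and 0.03, and the call of Mylk2 ended (-0.26). Sln, which encodes the calcium pump inhibitor sarcolipin, rose from 0.358 ± 0.136 to 5.41 ± 1.74 CPM (3.89, SE 0.380). The calcium release channel gene Ryr1 fell from 4956 ± 254 to 2540.1 ± 812 CPM (-0.96, SE 0.224), a call that ended without WT 2 (-0.98) or dEx51 5 (-0.91).

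Genes of the dystrophin-associated complex did not pass the set test. Of 16 tested, 1 rose (Sntb1) and 3 fell (Nos1, Sgca and Utrn), also adjusted over the list alone (median log2 fold change 0.04, camera adjusted p = 0.974), and the median was 0.08, 0.12 and -0.05 without dEx51 4, 5 and 6. Sntb1, a syntrophin gene, rose from 9.62 ± 1.01 to 22.3 ± 4.02 CPM (1.21, SE 0.159), and Nos1, the neuronal nitric oxide synthase that binds this complex, went from 204 ± 30.8 to 120 ± 20.4 CPM (-0.77, SE 0.155). Utrn, the dystrophin homologue utrophin, was at 94.6 ± 2.36 and 75.8 ± 7.02 CPM (-0.32, SE 0.0933, edgeR adjusted p = 0.0367). Sgca was at -0.41 (SE 0.120, edgeR adjusted p = 0.0363). Both genes were named after their values were seen, and both lay near the threshold. Scaled to library size alone, 9 members of the list were called higher and 0 lower, or 10 and 1 adjusted over the list alone. Over all genes the lower calls of Nos1 (-0.42), Utrn and Sgca thus ended. Of 12 membrane repair genes, 5 rose and 1 fell, also adjusted over the list alone (median 0.12, mean 0.76, camera adjusted p = 1.26e-05, adjusted p = 0.129 with an estimated correlation). The risers were annexins and myoferlin, among them Anxa4 (2.11, SE 0.109), Anxa1 (2.51, SE 0.159) and Myof (1.81, SE 0.138), while Capn3 was called lower (-0.36, SE 0.103) and lost that call without WT 1 (-0.36), WT 2 (-0.37), WT 3 (-0.37), dEx51 4 (-0.35) or dEx51 5 (-0.27), and under library-size scaling (-0.015). The median of this list was 0.07 without WT 3, 0.05 without dEx51 4 and 0.21 without dEx51 6. Of 13 neuromuscular junction and denervation genes, 4 rose and 0 fell, also adjusted over the list alone (median 0.38, camera adjusted p = 0.00513, adjusted p = 0.129 with an estimated correlation). Runx1 rose from 3.58 ± 1.43 to 27.2 ± 7.36 CPM (2.95, SE 0.299), and the receptor subunit genes Chrnd and Chrnb1 by 1.84 (SE 0.233) and 0.74 (SE 0.10). Of 15 atrophy and autophagy genes, 2 rose and 2 fell, also adjusted over the list alone, with no call of the list (median -0.09, camera adjusted p = 0.358, and 0.26 as the median under library-size scaling). Leaving out each library in turn, its median ran from -0.25 without WT 1 to -0.02 without dEx51 4. Mstn, which encodes myostatin, fell from 62.9 ± 12.2 to 29.6 ± 8.62 CPM (-1.09, SE 0.229), and the lysosomal protease gene Ctsl rose (0.89, SE 0.107), with 26.9% of its exon bases opposite another gene.

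The unfolded protein response list passed the set test with 8 members called, and its call depended on single libraries. Of 15 unfolded protein response genes, 8 rose and 0 fell, or 9 and 1 adjusted over the list alone (median log2 fold change 0.54, camera adjusted p = 0.0360, adjusted p = 0.455 with an estimated correlation). The risers were chaperone and folding genes such as Sdf2l1 (2.03, SE 0.325), Manf (1.12, SE 0.212) and Pdia6 (0.97, SE 0.184). The list lost its call without WT 1, WT 3, dEx51 4 or dEx51 5 (medians 0.58, 0.54, 0.44 and 0.54), and under library-size scaling (0.90). Of 17 interferon-stimulated genes, 4 rose and 0 fell, also adjusted over the list alone, with no call of the list (median 0.50, camera adjusted p = 0.0839). It passed without WT 3 (0.79) or dEx51 4 (0.64), and without dEx51 5 the median was 0.11. Oasl2, an antiviral gene, rose from 5.01 ± 0.879 to 15.6 ± 5.49 CPM (1.65, SE 0.262). Of 15 immediate-early genes, 4 rose and 0 fell, also adjusted over the list alone (median 0.39, camera adjusted p = 0.0368, adjusted p = 0.306 with an estimated correlation), led by Atf3 (2.23, SE 0.258). Its median was 0.63 without WT 1, 0.22 without WT 2, where the call ended, and 0.69 without WT 3, and under library-size scaling the call ended (0.74). Of 15 circadian clock genes, 0 rose and 2 fell, also adjusted over the list alone (median -0.36, camera adjusted p = 0.0428, adjusted p = 0.391 with an estimated correlation). Dbp was at -0.72 (SE 0.169), without WT 2 or dEx51 5 no longer called (-0.69 and -0.67), and the list lost its call without WT 1 (-0.43) or dEx51 5 (-0.38). Under library-size scaling the median of the clock list was -0.02, with 0 members called and Dbp at -0.38. With a correlation estimated from the data, 0 of the 30 lists passed the set test, against 22 with the preset correlation.

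**Figure D2:**
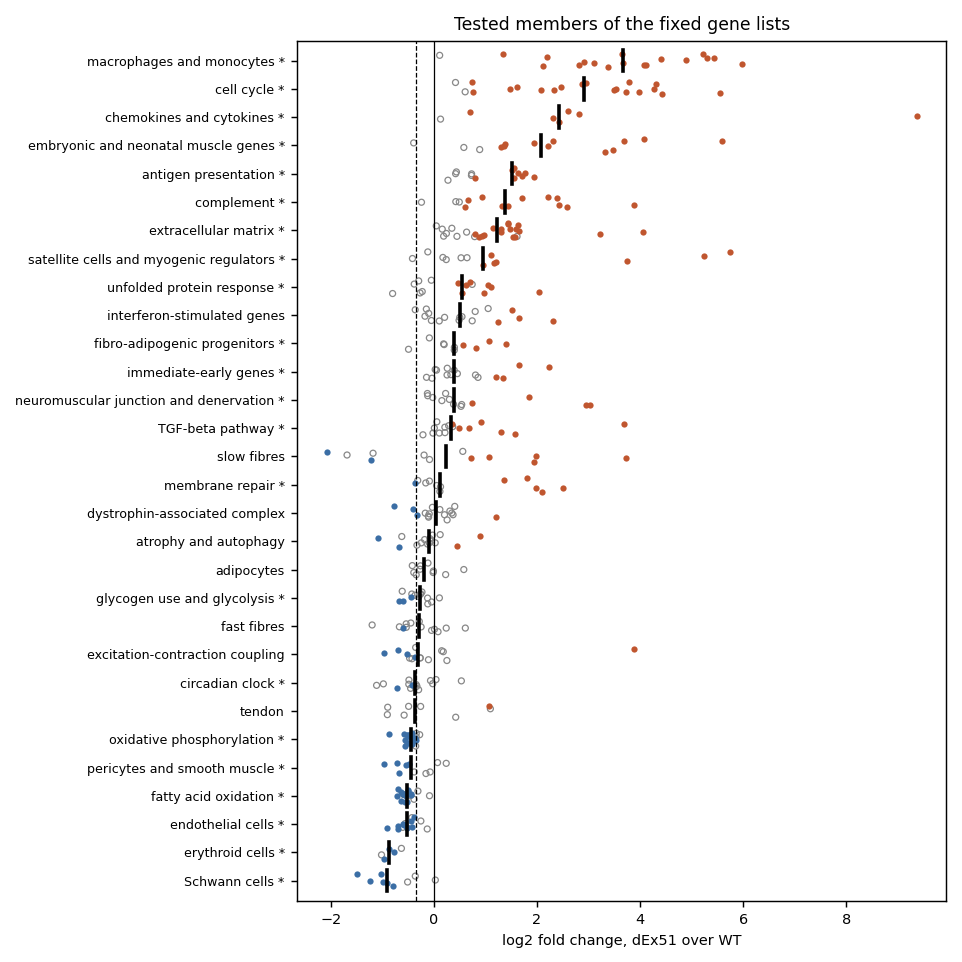
Each point is a tested member of a gene list, with its log2 fold change of dEx51 over WT on the x axis. Filled points passed the per-gene test (orange higher, blue lower), open points did not, vertical bars are list medians, asterisks mark the 22 of 30 lists past the set test with a preset correlation, the dashed line is where 0 would lie under library-size scaling, and the point at 9.37 is Il1rn, a fitted value for a gene with 0 counts in WT.

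**Figure D3:**
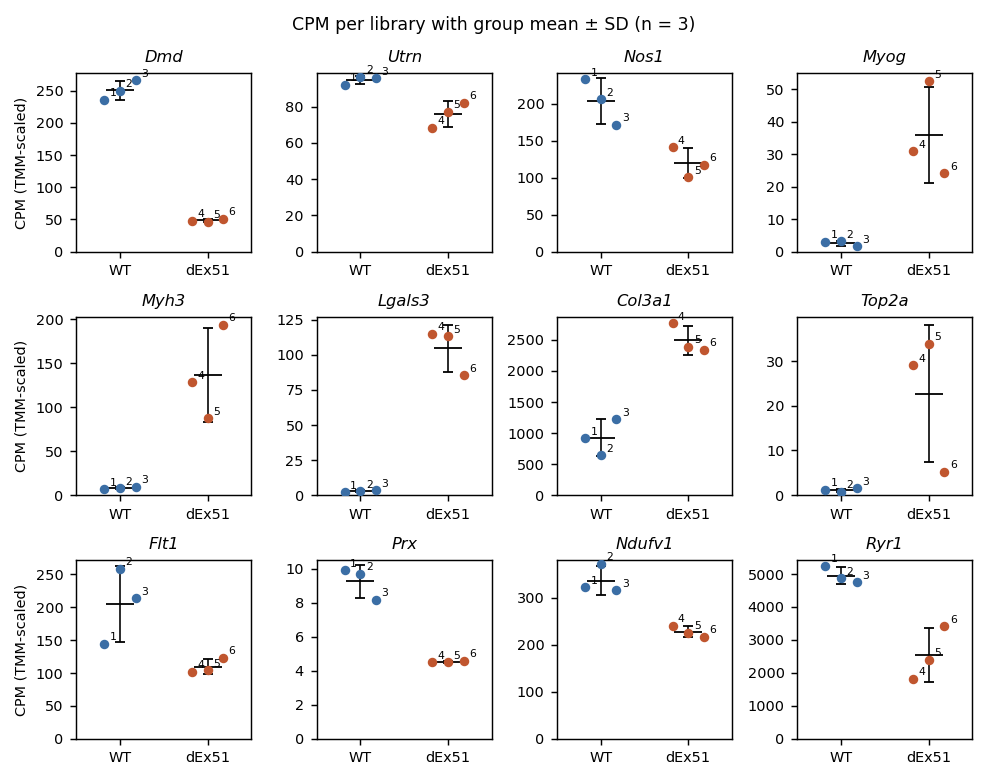
Points are TMM-scaled CPM (y axis, linear) of each library for 12 genes, by genotype on the x axis and marked with the library number, and bars show the group mean ± SD (n = 3). Dmd lies at 46.4 to 51.1 CPM in dEx51 and 235 to 266 CPM in WT, and Top2a at 5.30 CPM in dEx51 6 lies below the other dEx51 libraries.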

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

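The likelihood-ratio test and the joint removal of WT 1 and dEx51 4 were chosen after the results were seen. The fall of Dmd kept its direction and its call under all 21 alternatives run for it (-2.42 to -1.65). DESeq2 size factors, TMM without the 20 most abundant genes, the stricter filter, the exact test, the robust fit and the likelihood-ratio test left the counts of genes within 1.5 times and each of the 30 lists with a set test on its side of the threshold. Scaling set the split: library size alone gave 5394 higher and 334 lower. Limma-trend on RPKM, which changes the test, the genes and the scaling together, gave 5222 and 308 (pseudocount 0.1) or 5070 and 308 (pseudocount 1). An adjusted p under 0.01 left 1182 and 504 genes, a change of at least 1 log2 unit 1346 and 195, and removal of WT 1 with dEx51 4 1440 and 686.

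Under library-size scaling the medians turned for adipocytes (0.17), fast fibres (0.058), glycolysis (0.065), excitation-contraction coupling (0.029), atrophy (0.26) and Lipe (0.016), and the calls of the unfolded protein response (0.90) and immediate-early genes (0.74) ended. On RPKM with pseudocount 0.1 the values were adipocytes 0.063, tendon 0.034, fast fibres 0.054, glycolysis 0.063, coupling 0.024, atrophy 0.26, unfolded protein response 0.87 and immediate-early genes 0.79. With pseudocount 1 they were 0.051, 0.032, 0.054, 0.063, 0.024, 0.26, 0.83 and 0.44, and Lipe was 0.0029. The potassium channel list, added after seeing the data, turned to 0.069 at library size and to 0.013 and 0.0041 on RPKM.

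Lists that passed only under an alternative were slow fibres (0.25 with no filter, 0.23 with DESeq2), fast fibres (-0.27 with no filter, -0.29 with DESeq2, -0.36 with quality weights), interferon-stimulated genes (0.52 with no filter, 0.49 with DESeq2, 0.52 with voom, 0.60 with quality weights), coupling (-0.37 with quality weights) and T, NK and B cells (1.58 with no filter, where more members are tested). The unfolded protein response lost its call without WT 1 and dEx51 4 (0.49). The cause was not tested for these changes.

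With an estimated correlation 0 lists passed, at unchanged medians: satellite 0.96, embryonic 2.07, macrophages 3.66, chemokines 2.43, complement 1.38, matrix 1.22, fibro-adipogenic 0.40, TGF-beta 0.32, endothelial -0.53, pericytes -0.44, Schwann -0.91, erythroid -0.86, glycolysis -0.28, oxidative phosphorylation -0.44, fatty acids -0.53, junction 0.38, membrane repair 0.12, cell cycle 2.92, antigen presentation 1.51, unfolded protein response 0.54, clock -0.36 and immediate-early 0.39. With fry, 16 lists passed, and erythroid (-0.86), glycolysis (-0.28), cell cycle (2.92), antigen presentation (1.51), unfolded protein response (0.54) and clock (-0.36) did not.

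Leaving out each library in turn gave 1346 to 2662 higher and 663 to 2157 lower genes. Medians ranged over -0.050 to 0.12 for the dystrophin-associated complex, -0.52 to 0.14 adipocytes, -1.04 to -0.65 erythroid, 0.19 to 0.48 slow fibres, -0.42 to -0.21 fast fibres, -0.36 to -0.17 glycolysis, -0.44 to -0.21 coupling, 0.11 to 0.79 interferon, 0.44 to 0.63 unfolded protein response, -0.51 to -0.29 clock and 0.22 to 0.69 immediate-early genes.

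The replicate numbers were not taken to pair the libraries. Across all genes, deviations from the group mean correlated at 0.35, -0.01 and 0.06 for the same-numbered pairs, and not every library correlated best with its own number. The 0.35, of WT 1 and dEx51 4, was the highest of all pairs. Over clock genes alone the same-numbered pairs correlated at 0.887, 0.862 and 0.644, though WT 3 was slightly closer to dEx51 5 (0.652). A link between same-numbered libraries therefore stays open. A replicate block gave 2508 higher and 1960 lower genes, and the fast fibre list passed (-0.29).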

Other observations

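The gene lists of the next 2 paragraphs and all tests in this part except the count of splits were chosen after the results were seen. Transcripts of the mitochondrial genome were lower in dEx51. Of 13 protein-coding genes, 0 rose and 11 fell (median log2 fold change -0.93, camera adjusted p = 4.78e-11, adjusted p = 0.143 with an estimated correlation), and under library-size scaling the median was -0.58 with 10 called lower. The complex I gene mt-Nd4 was at 23393 ± 1321 CPM in WT and 12301 ± 517 CPM in dEx51 (-0.93, SE 0.157). Counting within this genome was uneven, since mt-Co3 was at 26.3 ± 5.85 CPM and mt-Co1 at 43593 ± 3160 CPM in WT. Of 11 cathepsin genes tested, the proteases of the lysosome, 9 rose and 0 fell (median 0.89, camera adjusted p = 1.08e-07, adjusted p = 0.136 with an estimated correlation). Ctsz rose by 1.63 (SE 0.138), Ctsh by 2.02 (SE 0.245) and Ctsb from 294 ± 11 to 772 ± 185 CPM (1.40, SE 0.169), and Ctss and Ctsl are also held by other lists.

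Of 16 imprinted genes, 9 rose and 0 fell (median log2 fold change 0.88, camera adjusted p = 4.81e-08, adjusted p = 0.130 with an estimated correlation). H19 rose from 880.3 ± 248 to 2259 ± 159 CPM (1.36, SE 0.209), Peg3 from 58.6 ± 5.13 to 199.98 ± 31.2 CPM (1.77, SE 0.135), and the growth factor gene Igf2 from 0.931 ± 0.318 to 4.39 ± 1.00 CPM (2.21, SE 0.301). Igf2 had 48 counts in WT, and 62.8% of its exon bases overlap other genes on the same strand, so its level is uncertain. Of the 16 imprinted genes H19, Igf2 and Dlk1 are also held by the embryonic muscle list, Sgce by that of the dystrophin-associated complex and Dcn by that of the matrix. Potassium channel genes moved both ways, with 10 of 45 higher and 12 lower (median -0.26, mean 0.02, camera adjusted p = 0.174), and the median was 0.07 under library-size scaling. Within the calcium-activated Kcnn family, Kcnn4 (3.31, SE 0.370) and Kcnn3 (1.56, SE 0.261) rose and Kcnn2 (-1.33, SE 0.180) and Kcnn1 (-0.79, SE 0.0964) fell, while Kcnj2, an inward rectifier, fell from 84.1 ± 12.3 to 34.7 ± 5.76 CPM (-1.28, SE 0.151). Kcnj8 is also held by the pericyte list.

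Library-size scaling moved the vessel, Schwann cell and metabolic lists by about the all-gene shift of 0.35, so whether a median stayed below 0 depended on the size of its fall. Under that scaling the Schwann cell median was -0.57 (95% interval over genes -0.89 to -0.02) with every dEx51 library below every WT library. The Schwann cell fall was thus present under either scaling. Its larger size under TMM (-0.91) made this outcome likely, and both scalings are relative, so an absolute fall was not tested. The endothelial (-0.17, -0.25 to -0.07), pericyte (-0.10, -0.35 to 0.42), oxidative phosphorylation (-0.084, -0.16 to -0.0041) and fatty acid (-0.17, -0.24 to -0.09) medians had overlapping libraries, so for them scaling and an absolute fall cannot be told apart. These lists stayed lower relative to other genes in camera, but a shared shift largely cancels in that test, so it does not decide the question. Dilution by RNA of other cells would move the endothelial, pericyte, Schwann cell, adipocyte, tendon and fast fibre lists together. Their medians spanned 0.72, from Schwann cells to adipocytes (permutation p = 0.00568, 65 genes, 100000 resamples). The permutation took genes as independent, so its p does not measure spread between mice. Members of some lists vary together, with an estimated correlation of 0.639 in adipocytes and 0.645 in tendon, though -0.00016 in Schwann cells. The permutation p was also 0.0582 without the Schwann cell list, 0.0659 without the adipocyte list and 0.0995 without WT 1. Dilution and separate falls therefore cannot be told apart. A change of genotype-related tissue makeup stays open as an untested explanation.

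In dEx51 6 the rise of 18 cell-cycle genes reached a median of 14.3% (interval over genes 11.99 to 19.98) of that in dEx51 4 and dEx51 5. A mixture with unaffected muscle would lower every rise alike, but the rise of 11 embryonic muscle genes reached 136% (94.7 to 181), which argues against it for these genes. The genes of both lists equal in number those called higher, in a test that included dEx51 6. The intervals are over genes and not over animals. Csrp3, an embryonic list member that was not called, was at 51.1, 93.8 and 9.76 CPM in dEx51 4, 5 and 6, against 34.5 CPM in WT. It was chosen after its values were seen. The macrophage, complement and matrix genes reached 54.9% (44.2 to 63.7), 58.6% (43.7 to 199) and 79.5% (69.0 to 84.2). Single genes of these lists ranged from 25.5% to 192%, 36.6% to 264% and 14.5% to 203%. A different stage of injury and repair in that animal is a hypothesis that these data may allow but that was not tested.

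Clock genes of WT 1 and dEx51 4 deviated alike from their group means (r = 0.887 across 15 genes, which are not independent replicates), against 0.352 across all genes. The labels give both libraries the same replicate number. The other same-numbered pairs had clock correlations of 0.862 (WT 2 and dEx51 5) and 0.644 (WT 3 and dEx51 6). WT 2 with dEx51 6 (0.734) and WT 3 with dEx51 5 (0.652) were also alike, while the remaining pairs lay at -0.866 to -0.690. Nr1d1 was at 161 CPM in WT 1 and 59.7 CPM in dEx51 4, against 21.0 to 37.7 CPM in the others, and Per2 at 13.2 and 11.7 against 29.1 to 43.6 CPM. The highest of the 9 correlations lay at percentile 96.9 of 10000 random lists matched on expression (median 0.614), but the clock list was picked out from among 28 other lists, of which the unfolded protein response was as high, so a general likeness of the libraries and a shared hour of dissection, which the labels do not give, cannot be told apart, and no biological explanation was tested.

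Among the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 4010 called genes and the highest of the others 0 (edgeR). The splits are too few for a share under 0.05. Each of the other splits also mixes the genotypes within both groups, so a large difference between genotypes widens the spread there and makes calls unlikely. The 0 calls are therefore not read as evidence against chance.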
